A study of Mus musculus with 24 samples.

How the data were processed

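RNA was sequenced from white and brown adipose tissue of mice given scramblemiR, antimiR-224 or antimiR-452, with 4 libraries in each of 6 groups. Per the labels' protocols, RNA was extracted with Trizol, mRNA was selected with oligo-dT beads and libraries were made with a directional kit. The submitters' processing notes name the genome build GRCm38.p4, DESeq 1.10.1 and R 2.15.3. Aligner, counting tool and annotation release are not given in the sources used here. The labels call the libraries separate samples of a group and do not say that each came from a separate mouse, so p-values of tests between groups measure the spread between these samples. P-values of the random-list and seed-site tests compare genes by their deposited ratios and measure no spread between samples.

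The authors deposited 4 tables, 1 for each inhibitor and tissue against scramblemiR. Per the file headers, each holds a mean signal, the normalized count averaged over the libraries of each group, their ratio as deposited by the authors, its log2 as deposited, and the deposited p-value and adjusted p-value. The columns are group means and give no error between replicates directly. The deposited adjusted p-values equal Benjamini-Hochberg values recomputed from the deposited p-values within 3.7e-15. Each table was normalized separately, so control means differ slightly between both tables of a tissue. Of the identifiers, 99.42% to 99.48% matched a gene symbol. The results quoted as the authors' are taken from these tables, and the design written before the data were examined had assumed deposited counts for a count-based test.

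Reads per library were recovered from the printed means, an alternative chosen after the data were seen. A group mean is the sum of 4 whole read numbers, each divided by 4 times the size factor of its library, printed to about 15 digits. The size factors were solved from low genes and each mean was then decoded into 4 whole numbers. Controls occur in 2 tables with different size factors, which gave a unique solution for 100% of genes. In the inhibitor groups 89.92% to 93.20% of genes had a unique solution, and most genes above a mean of 2000, or of 1500 in the BAT antimiR-224 group, had several and were left out. Means rebuilt from recovered reads matched the deposited means within a relative error of 5.2e-15. On simulated data of the same sizes, 0 decoded solutions were wrong, and 90.79% to 93.11% of genes in the simulated inhibitor groups were recovered. No pair of libraries agreed within sampling noise, since chi-square per degree of freedom was at least 11.4. The file headers number the libraries of each mean, but recovered reads cannot be tied to a header number or a sample title, so libraries are numbered by descending size factor.

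Recovered normalized counts were tested with limma 3.58.1 in R 4.3.3 on log2(count + 1), with trend and robust variance, genes with a mean of at least 10, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates changes of low genes. The test was checked on simulated data with 100 genes changed at each fold. It called 77% to 92% of 4-fold changes and 21% to 65% of 2-fold changes, with 4 to 12 false calls. The simulated genes varied independently, with a spread that followed their mean, and no simulated library stood apart. Some real libraries did, so these shares may not hold for the real data. In a simulated interaction outside limma 182 of 200 changed genes were called, with 8 false calls and 5.31% of unchanged genes at an unadjusted p under 0.05. The limma interaction was not checked on simulated data. Real deposited ratios gave a smaller share at that p, 235 of 14152 and 128 of 14275 genes. The simulated share called therefore does not carry over to them. Of the 12 header numbers in WAT, 7 recur in BAT, each in the group of the same treatment (2 scramblemiR, 2 antimiR-224, 3 antimiR-452), so some mice may have given both tissues, which the labels do not state. Interaction tests treated the tissues as independent. They used the same model over both tissues for the genes recovered in both, and also a comparison of deposited ratios with standard errors taken from the deposited p-values. The deposited columns hold no counts, and tests made for counts were not run on the recovered reads, which lack most abundant genes of the inhibitor groups. Other settings were pseudocounts of 0.5 and 5, minimum means of 0 and 50, no robust variance, each library left out in turn, and the libraries high in epithelium, germ cell or muscle genes left out. These libraries were picked by hand after their values were seen, and the BAT inhibitor libraries were added to that choice after a first fit without only the 2 controls.

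Fixed before the data were examined were 25 lists of genes by function and 16 of cell type markers. A list's median log2 ratio from the deposited tables was set against 10000 random lists of the same size matched on mean expression in 20 classes, for genes with a mean of at least 10 and lists with 3 or more members. This percentile test takes no account of the spread between libraries. The smallest p it can give is 2.00e-04. With log2 ratios shuffled across genes, it called 3.00% to 6.00% of unchanged simulated lists and at least 99.5% of lists shifted by 0.5. Shuffling removes variation that genes share, so these shares do not carry over to real lists whose members vary together. Lists were also tested with limma's camera on recovered reads, with correlation preset to 0.01 and with an estimated correlation, adjusted over all lists with 3 or more recovered members, added lists included. Counts of lists called by camera are adjusted over the fixed lists alone. Added after the data were seen were 4 lists: ciliated epithelium, transporting tubule epithelium, male germ cell and less abundant skeletal muscle genes. Geometric means per library use log2(count + 1) over the members recovered in all 12 libraries of a tissue.

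The overlap of both inhibitors was simulated after the data were seen, in 100 simulated data sets with genes drawn independently and ordered by their log2 difference over its standard error plus the median standard error.

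Seed sites were searched in 3' untranslated regions of the longest annotated form per gene in GENCODE M21 (GRCm38), derived from stop codons and exons. A stop codon preceded the derived region in 44883 of 44883 transcripts, and 20916 genes had a region of at least 30 bases. Genes with a site were compared with genes without by permutation within classes of length and mean. With log2 ratios permuted across genes, a simulated shift of 0.05 was called in 20 of 20 repeats and none in 20 repeats without a shift.

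Named genes follow a rule fixed beforehand: the 10 rising and 10 falling genes with the largest change past an adjusted p of 0.05 and a mean of at least 50, up to 4 such members of each list, the genes with the smallest p, up to 10, where fewer than 10 pass, and Gabre, Adipoq, Lep, Ucp1, Fasn, Slc2a4, Insr and Smad4 whatever their p. Some are left out for length, and 1 gene that the rule names is not reported here. Exceptions, chosen after their values were seen, are Arntl, Npas2, Cry1, Clock, Nfil3, Dbp, Ifit1, Isg15, Myh4, Acta1, Prm1, Hba-a1, Eif2s3y, Ddx3y and, outside WAT with antimiR-224, Cilp, Atp6v0a4 and Dmkn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.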

Results

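Messenger RNA was sequenced from white adipose tissue (WAT) and brown adipose tissue (BAT) of C57BL/6 mice. The mice had received 2 injections under the skin of 25 mg/kg of an LNA-modified oligonucleotide directed against miR-224 (antimiR-224), against miR-452 (antimiR-452) or of scrambled sequence (scramblemiR). LNA, locked nucleic acid, is a modified nucleotide that makes such an oligonucleotide bind its microRNA tightly. Each tissue had 3 groups of 4 libraries, 24 libraries in all. The series title links oestrogen with circulating levels of both microRNAs, and the comparisons ask which transcripts differ in fat once either microRNA is inhibited. Mature microRNAs are not measured by libraries selected on poly(A) tails, so inhibition itself could not be checked here.

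The deposited tables gave the mean normalized count of each group of 4, and reads per library were recovered from these means. The 4 WAT scramblemiR libraries held between 22175430 and 27935908 reads in genes, and the 4 BAT scramblemiR libraries between 16960694 and 20255777. Totals of the inhibitor libraries are unknown, because their abundant genes could not be recovered. The headers of the deposited tables number the 4 libraries behind each mean, with numbers that differ from those in the sample titles. Recovered reads cannot be tied to either, so libraries are numbered here within each group by descending size factor.

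In WAT after antimiR-224, Cilp was the 1 gene of 29128 past an adjusted p of 0.05 in the authors' deposited table. Cilp, which encodes cartilage intermediate layer protein of the extracellular matrix, had a mean normalized count of 581 with scramblemiR and 1842 with antimiR-224 in the authors' deposited table. That is a log2 ratio of 1.67, with an adjusted p of 0.0193 and an unadjusted p of 6.62e-07. The gene (ENSMUSG00000042254) lies on chromosome 9, 65265180 to 65280605, plus strand, GRCm38. Its 4 recovered control values ran from 268 to 837, and its antimiR-224 values could not be recovered one by one. With antimiR-452 the authors' deposited table gives Cilp means of 584 and 1849 in WAT (adjusted p 0.344), a value looked up after the first was seen. In BAT, recovered Cilp counts were 1129, 684 and 893 in library 1 of the scramblemiR, antimiR-224 and antimiR-452 groups and 185 or less in every other library. No other gene passed, and 452 genes (326 higher, 126 lower) had an unadjusted p under 0.05. Where nothing differs, a share of about 0.05 of genes has such a p. The share was smaller in each of the 4 deposited tables and near 0.05 in limma's 4 comparisons with scramblemiR. The limma test on recovered reads called 0 of 15509 genes, with 927 at an unadjusted p under 0.05, but Cilp was not among the genes it could test.

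The genes next in order of p did not pass. Slc9a3r1, an anchor protein of epithelial membranes, had means of 661 and 1736 in the authors' deposited table (log2 1.39, adjusted p 0.198). Krt19, a keratin of simple epithelia and mesothelium, had means of 923 and 2069 there (log2 1.16, adjusted p 0.795), and Atp6v0a4, a proton pump subunit of epithelia, means of 65.2 and 345 (log2 2.40, adjusted p 1). Ezr, which links membranes to actin, and the semaphorin receptor Plxnb2 had log2 ratios of 1.31 and 0.89 in the authors' deposited table. Lower values were those of Clstn3, which has a role in adipocyte lipid storage, at 941 and 286 (log2 -1.72, adjusted p 0.795 in the authors' deposited table). Atp6v0a4 was at 38.5 to 112 in the controls and above them in every WAT inhibitor library, at 428, 459, 328 and 165 with antimiR-224 and 322, 517, 326 and 192 with antimiR-452. A two-sided exact permutation test, chosen after these values were seen, gave p = 0.0286 for each, the smallest that 4 against 4 can give. The gene was picked by its small p among 29128 genes, and both tests use the same 4 controls. With all values already apart the test had to give this p, so it adds no support. The epidermal secreted protein gene Dmkn (log2 2.23, adjusted p 1 in the authors' deposited table) was at 544, 658, 220 and 238 with antimiR-224 against 70.8 to 114 in the controls (p = 0.0286 by the same test, with the same limit). With antimiR-452 it was at 84.4 to 453 (exact permutation p 0.0857). In the recovered reads Clstn3 was 941 ± 356 (SD, n = 4) with scramblemiR and 286 ± 59.6 (SD, n = 4) with antimiR-224.

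Genes of lipid synthesis and energy metabolism had lower means in this comparison. Of the 18 fatty acid synthesis genes, 15 had a log2 ratio below 0, with a median of -1.03 against -0.08 for random lists matched on mean expression (adjusted p 5.86e-04 over 41 lists). Fasn, the fatty acid synthase, had means of 159360 and 39150 in the authors' deposited table (log2 -2.03, unadjusted p 0.0335, adjusted p 1). Its 4 control libraries ranged from 23700 to 302156. Of 55 nuclear genes of oxidative phosphorylation 54 were below 0 (median -0.34, adjusted p 5.86e-04, and 0.716 as the adjusted p with an estimated correlation). So were 20 of 24 of cholesterol synthesis (median -0.55, adjusted p 5.86e-04, and 0.639 likewise) and all 20 of the citric acid cycle (median -0.41, adjusted p 5.86e-04). Among recovered genes scramblemiR library 4 stood above the other controls: the geometric mean of 18 recovered oxidative phosphorylation genes was 1290 there, 584 to 837 in the other controls and 662 to 760 with antimiR-224. For 23 cholesterol synthesis genes it was 797 there, 395 to 498 in the other controls and 336 to 441 with antimiR-224. The insulin-responsive glucose transporter Slc2a4 had means of 5216 and 2415 in the authors' deposited table (log2 -1.11, unadjusted p 0.00295, adjusted p 1). The adjusted p with an estimated correlation between genes is that of limma's camera, for which too few fatty acid synthesis and citric acid cycle genes were recovered. Fatty acid oxidation (19 of 20 below 0, median -0.38, adjusted p 5.86e-04, and 0.670 as the adjusted p with an estimated correlation, from 3 recovered members) and mature adipocyte genes (18 of 18 below 0, median -0.42, adjusted p 0.00103, not testable by camera) lay the same way. No member of these lists passed when p was adjusted over the list alone.

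Interferon response genes lay above 0 in 25 of 26 cases (median log2 0.92, adjusted p 5.86e-04, and an adjusted p of 0.741 with an estimated correlation). Their geometric mean was 481 and 1253 normalized counts in antimiR-224 libraries 3 and 4, against 223 and 248 in libraries 1 and 2 and 219 to 351 in the controls. The antiviral effector Ifit1, named after its values were seen, had means of 277 and 814 in the authors' deposited table (log2 1.55, adjusted p 1). Macrophage markers had a median of 0.47 (18 of 20 above 0, adjusted p 5.86e-04, and 0.631 as the adjusted p with an estimated correlation), and mast cell markers 0.93 (7 of 7 above 0, adjusted p 0.0125, and 0.631 likewise). The mast cell geometric mean was 220 and 258 in antimiR-224 libraries 1 and 2, but 106 and 117 in libraries 3 and 4, within the 55.2 to 124 of the controls. Mesothelial markers had a median of 0.78, with 12 of 12 above 0 and 1 past the threshold adjusted over the list alone (adjusted p 5.86e-04, and 0.715 as the adjusted p with an estimated correlation). The geometric mean of 3 recovered mesothelial genes was 1178 and 647 in antimiR-224 libraries 3 and 4 and 369 and 337 in libraries 1 and 2. It was 93.3 in scramblemiR library 4 and 362 to 615 in the other controls. In all, 25 of 41 lists, 11 higher and 14 lower, passed this test, which takes no account of the spread between libraries. None of the lists that camera could test passed with an estimated correlation.

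In WAT after antimiR-452, 0 of 29079 genes passed an adjusted p of 0.05 in the authors' deposited table, where the lowest adjusted p was 0.148 and 702 genes (671 higher, 31 lower) had an unadjusted p under 0.05. The limma test on recovered reads also called 0 of 15550, with 726 at an unadjusted p under 0.05. Without antimiR-452 library 4, which was low in the epithelium lists described further on, it called 543 genes, 540 of them higher. Several of the genes with the smallest p are known from epithelia, and none passed. The glycosyltransferase B4galnt2 had means of 3.23 and 197 in the authors' deposited table (log2 5.93) and the sodium-proton exchanger Slc9a3 4.13 and 179 (log2 5.44). The steroid 5-alpha-reductase Srd5a2 had means of 7.24 and 220 there (log2 4.93) and the dynein heavy chain Dnah5 of motile cilia 28.3 and 626 (log2 4.47), each with an adjusted p of 0.148. The desmosome protein desmoplakin, Dsp, on chromosome 13 had means of 60.2 and 1201 there (log2 4.32, adjusted p 0.148). In recovered reads Dsp stood at 1473, 1857, 1452 and 23.3 in the 4 antimiR-452 libraries.

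All 8 erythroid genes measured were below 0 (median -2.79, adjusted p 9.11e-04), 7 of them past the threshold adjusted over the list alone and 0 over all genes tested. With an estimated correlation the adjusted p was 0.680. Markers of mammary epithelium, a list of which keratins, Epcam and Cdh1 are also expressed by other epithelia, had a median of 2.08 (7 of 7 above 0, 5 past the threshold adjusted over the list alone, adjusted p 9.11e-04, and 0.961 as the adjusted p with an estimated correlation). The geometric mean of 4 recovered members was 90.8 to 148 in antimiR-452 libraries 1 to 3, 29.4 in library 4 and 23.6 to 69.8 in the controls. Skeletal muscle genes had a median of 2.59 (17 of 18 above 0, adjusted p 9.11e-04, and 0.996 with an estimated correlation), which rested on library 3: Myh4, a fast myosin named after its values were seen, was at 4737 there and at 3.80 or less in the other antimiR-452 libraries. Fatty acid synthesis had a median of -0.68 (15 of 18 below 0, adjusted p 9.11e-04) and oxidative phosphorylation -0.25 (54 of 55 below 0, adjusted p 9.11e-04, and 0.996 with an estimated correlation). Fatty acid synthesis was not testable by camera here either, and the geometric mean of 18 recovered oxidative phosphorylation genes was 565 to 829 with antimiR-452, against 584 to 837 in scramblemiR libraries 1 to 3 and 1290 in library 4. Mesothelial markers had a median of -0.26 and a mean of 0.20, opposite in sign. The 5 epididymis genes measured had a median of 3.14 (4 above 0, adjusted p 0.00137, and 0.996 with an estimated correlation), and of 5.20 after antimiR-224 (4 above 0, adjusted p 5.86e-04, and 0.786 likewise). The geometric mean of 3 recovered epididymis genes was 96.3 in antimiR-452 library 1 and 0.759 to 4.89 in the others of that group, 187 in antimiR-224 library 2 against 1.76 to 7.24, and 74.2 in scramblemiR library 2 against 0 to 1.84. Interferon response genes, with a median of -0.06, did not pass (adjusted p 0.596). Of 41 lists 23 passed, 10 higher and 13 lower. With the mean in place of the median 5 did, and none with an estimated correlation.

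Marker lists of other tissues, written after the data were seen except for the erythroid list, separated libraries of the same group. Against matched random lists, ciliated epithelium genes had a median of 1.72 with antimiR-224 and 1.76 with antimiR-452, tubule epithelium genes 2.79 and 3.02 and sperm-lineage genes -1.42 and -4.78 (adjusted p 2.67e-04 each over the added lists). Because these lists were chosen after the data were seen, such a small p is no support for a difference. With an estimated correlation the adjusted p was 0.670 and 0.996, 0.639 and 0.889, and 0.786 and 0.996. The geometric mean of 16 ciliated epithelium genes was 501 and 600 in antimiR-224 libraries 1 and 2 but 54.5 and 20.1 in libraries 3 and 4. It was 301, 488 and 378 in antimiR-452 libraries 1 to 3 but 3.27 in library 4, and 3.20 to 167 in the controls. Transporting tubule epithelium genes, 12 recovered, were high in these 5 libraries (247 to 372) and at 6.05 to 42.2 in every other WAT library. The male germ cell list of sperm-lineage genes, 20 recovered, was at 1635 in scramblemiR library 2 and at 410 and 106 in antimiR-224 libraries 3 and 4. Both its -1.42 and its -4.78 rest on that control library: the other 3 controls were at 1.41 to 3.48, the other antimiR-224 libraries at 18.1 and 32.2 and the antimiR-452 libraries at 34.6, 20.9, 8.57 and 1.13. On log2 values of recovered reads, where each library counts alike, the median was 2.46 with antimiR-224, opposite in sign, and -0.66 with antimiR-452. Without the 2 antimiR-224 libraries high in epithelium genes limma called 0 genes (489 at an unadjusted p under 0.05). That fit keeps just antimiR-224 libraries 3 and 4, which are high in sperm-lineage genes, as is control library 2, and so says little. Leaving out the 3 antimiR-452 libraries high in epithelium genes keeps 1 antimiR-452 library, so no count is given for that fit. Without the 3 libraries high in sperm-lineage genes limma called 1245 for antimiR-224, a fit that keeps just the 2 antimiR-224 libraries high in epithelium genes. The erythroid geometric mean ran from 99.2 to 638 in the controls and from 36.0 to 118 with antimiR-452.

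**Figure D1:**
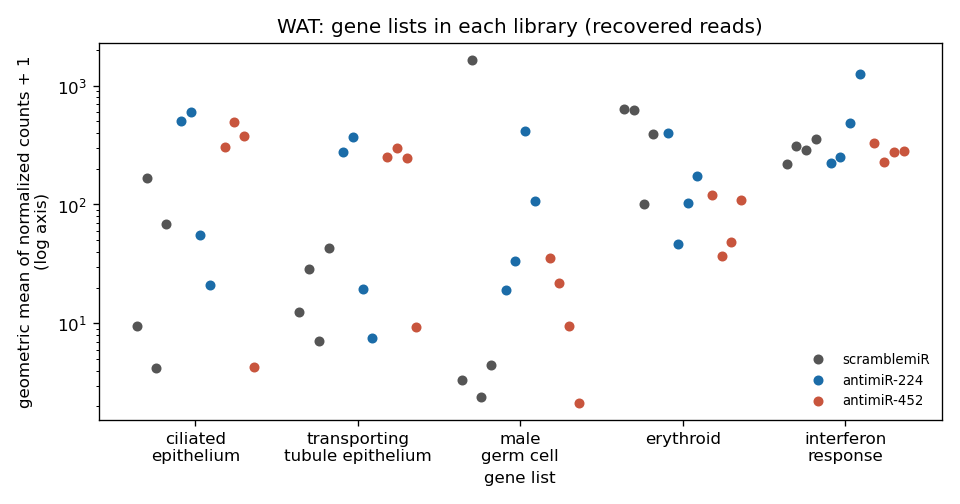
Geometric mean of normalized counts, with 1 added for the log axis, of 5 gene lists (x axis) in the 12 WAT libraries, 1 point per library, from recovered reads. Before that 1 is added, ciliated and tubule epithelium genes reach 247 or more in 2 antimiR-224 and 3 antimiR-452 libraries, and sperm-lineage genes 1635 in 1 scramblemiR library.

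In BAT after antimiR-224, 0 of 24084 genes passed in the authors' deposited table, where every adjusted p was 1 and 276 genes (115 higher, 161 lower) had an unadjusted p under 0.05. The limma test on recovered reads called 0 of 12109, with 702 at an unadjusted p under 0.05, 406 of them higher. Irs2, an adaptor of the insulin receptor, had means of 3452 and 1363 in the authors' deposited table (log2 -1.34, unadjusted p 0.00146).

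Immediate early genes, transcription factors induced within minutes of a stimulus, were below 0 in 17 of 18 cases in this comparison (median -0.73, adjusted p 0.00106, and 0.667 as the adjusted p with an estimated correlation). The geometric mean of 15 recovered members was 329, 502, 678 and 248 in the controls and 388, 195, 174 and 167 with antimiR-224. Nuclear genes of oxidative phosphorylation were above 0 in 53 of 55 (median 0.55, adjusted p 0.00106). Just 4 of them were recovered, which gave an adjusted p of 0.716 with an estimated correlation and lay at 115 to 289 in the controls and 123 to 257 with antimiR-224. Collagens and matrix genes were below 0 in 25 of 28 (median -0.36, adjusted p 0.00106, and 0.716 with an estimated correlation). Control libraries 1 and 3 carried that difference: the geometric mean of 16 recovered members was 672 and 821 there, 416 and 338 in the other controls and 554, 399, 349 and 328 with antimiR-224. Insulin signalling and glucose uptake had a median of -0.23 (19 of 22 below 0, 1 past the threshold adjusted over the list alone, adjusted p 0.0164, and 0.667 with an estimated correlation). Macrophage markers had a median of -0.44 (17 of 19 below 0, adjusted p 0.00278, and 0.776 with an estimated correlation), with 151, 79.1, 173 and 63.2 in the controls and 138, 56.0, 53.5 and 96.3 with antimiR-224. B cell markers had a median of 1.59 (5 of 5 above 0, adjusted p 0.00106, and 0.716 likewise) and were at 133 in library 1 against 10.2 to 23.6 in the others of that group. All 20 skeletal muscle genes lay below 0 (median -1.78, adjusted p 0.00106, not testable by camera). In all 10 of 37 lists passed, 4 higher and 6 lower, and none with an estimated correlation.

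In BAT after antimiR-452, 0 of 24248 genes passed in the authors' deposited table, where every adjusted p was 1 and 121 genes (46 higher, 75 lower) had an unadjusted p under 0.05. The limma test called 0 of 13023, with 551 at an unadjusted p under 0.05. Irs2 had the smallest p here, with means of 3476 and 951 in the authors' deposited table (log2 -1.87, unadjusted p 5.99e-04). Its recovered values were 1850 to 5087 in the controls and 776 to 1305 with antimiR-452. Irf4, a transcription factor with a role in thermogenic fat, had means of 2733 and 682 in the authors' deposited table (ratio 0.249, unadjusted p 0.00599), and the lincRNA Gdap10 means of 352 and 110 (log2 -1.67, unadjusted p 0.00165).

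All 26 interferon response genes were above 0 in this comparison (median 0.69, adjusted p 0.00109, and 0.374 as the adjusted p with an estimated correlation). Their geometric mean was 72.3 to 147 normalized counts in the controls and 111 to 210 with antimiR-452. The antiviral genes Isg15 and Ifit1, named after their values were seen, had log2 ratios of 1.30 and 1.47 in the authors' deposited table (unadjusted p 0.0280 and 0.0306, adjusted p 1 each). Immediate early genes were below 0 in 17 of 18 (median -0.82, adjusted p 0.00109, and 0.493 with an estimated correlation), at 157 to 327 with antimiR-452 against 248 to 678 in the controls. Brown fat thermogenic genes were below 0 in 15 of 20 (median -0.34, adjusted p 0.00109, and 0.374 with an estimated correlation), and the 8 recovered were at 323 to 452 against 482 to 733. Insulin signalling and glucose uptake was below 0 in 14 of 22 (median -0.33, adjusted p 0.00109, and 0.596 likewise). Its 10 members recovered in every BAT library were at 731 in antimiR-452 library 1 and 493 to 506 in the others, against 585 to 784 in the controls. Oxidative phosphorylation was above 0 in 52 of 55 (median 0.60, adjusted p 0.00109), with an adjusted p of 0.599 with an estimated correlation from just 4 recovered members, at 194 to 287 against 115 to 289. Skeletal muscle genes had a median of 0.53 (19 of 20 above 0, adjusted p 0.00109, not testable by camera). Of 38 lists 10 passed, 5 higher and 5 lower, and none with an estimated correlation.

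BAT libraries of the same group differed in skeletal muscle transcripts. The geometric mean of 12 less abundant muscle genes, a list written after the data were seen, was 664 and 420 normalized counts in scramblemiR libraries 1 and 2 and 2.23 and 1.91 in libraries 3 and 4. It was 254 in antimiR-224 library 1 and 1318 in antimiR-452 library 1, with 5.45 to 7.50 and 1.24 to 64.4 in the others. Its median log2 ratio was -1.85 with antimiR-224 (adjusted p 4.00e-04 over the added lists, and 0.810 with an estimated correlation) and 0.44 with antimiR-452 (0.00640, and 0.970). For a list chosen after the data were seen, a small p over the added lists is no support for a difference. The 20 muscle genes of the fixed list took 6.66% and 6.69% of all gene reads in scramblemiR libraries 1 and 2 and 0.0185% and 0.0207% in libraries 3 and 4. Without those 2 controls and library 1 of the inhibitor group, limma called 0 genes in either BAT comparison, with 562 and 435 at an unadjusted p under 0.05. Each fit keeps just control libraries 3 and 4, so its 0 says little. Of the antimiR-452 libraries kept, 2 and 4 still held more muscle transcripts (22.2 and 64.4) than these controls, and library 3 did not (1.24).

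**Figure D2:**
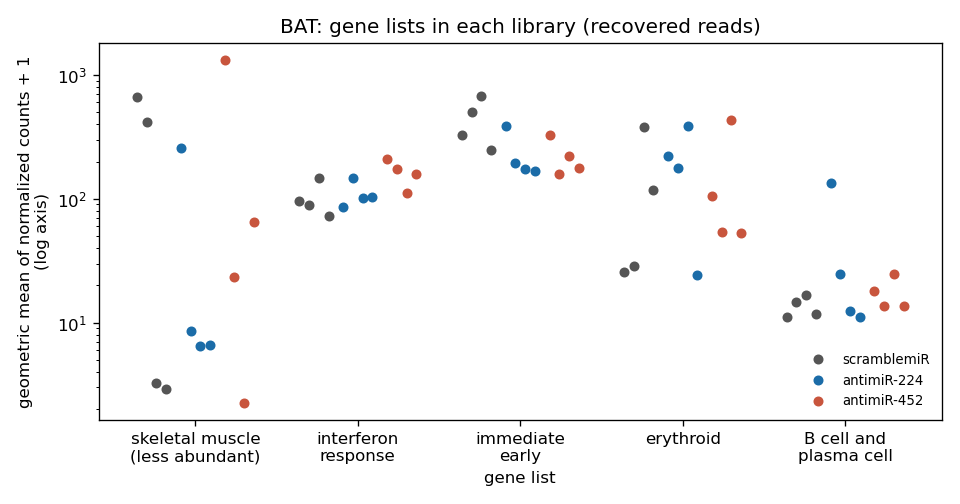
Geometric mean of normalized counts, with 1 added for the log axis, of 5 gene lists (x axis) in the 12 BAT libraries, 1 point per library, from recovered reads. Before that 1 is added, muscle genes span 1.24 to 1318 between libraries, while interferon response genes stay between 72.3 and 210.

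Gabre, whose introns hold both microRNAs, did not differ in any comparison at an unadjusted p of 0.05. The authors' deposited tables list means of 151 and 188 in WAT with antimiR-224, 152 and 163 with antimiR-452, and in BAT 17.2 and 8.76 and 17.3 and 23.2. The adipokines Adipoq and Lep, the uncoupling protein Ucp1, the insulin receptor Insr and Smad4 had an unadjusted p of 0.179 or more in each of the authors' 4 deposited tables. In BAT, Ucp1 had means of 86679 and 96156 with antimiR-224 and 87305 and 74998 with antimiR-452 in the authors' deposited tables.

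In WAT, Arntl, a core transcription factor of the circadian clock named after its values were seen, stood higher in each of the 8 inhibitor libraries than in any of the 4 controls. Recovered normalized counts were 59.8 ± 17.3 (SD, n = 4) with scramblemiR, 164 ± 25.5 (SD, n = 4) with antimiR-224 and 147 ± 39.9 (SD, n = 4) with antimiR-452. A two-sided exact permutation test gave p = 0.0286 for each inhibitor, the smallest that 4 against 4 can give, for a gene picked from all those seen, 15509 of which limma tested for antimiR-224. The authors' deposited tables give log2 ratios of 1.46 and 1.29 with adjusted p of 1 each. In BAT, Arntl had means of 84.6, 44.7 and 81.9 with scramblemiR, antimiR-224 and antimiR-452. The circadian clock list as a whole passed in none of the 4 comparisons. Clock genes of opposite phase can cancel in a list's median, so this result says little about a shift of the clock.

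**Figure D3:**
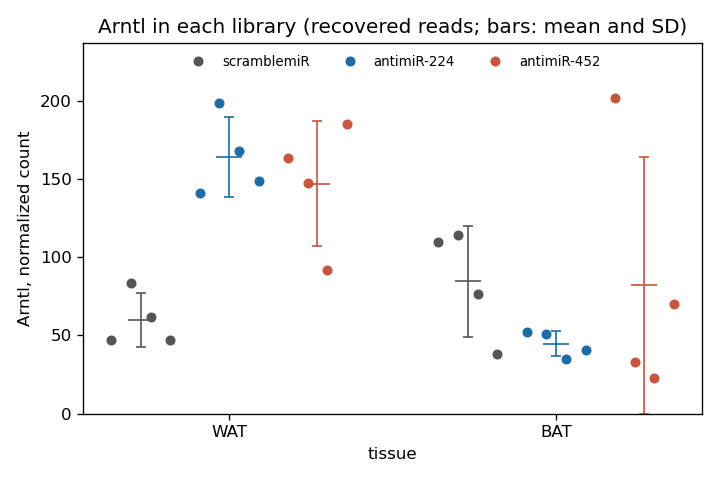
Normalized counts of Arntl (y axis) in the 12 WAT and 12 BAT libraries (x axis: tissue), 1 point per library by group, from recovered reads, with the mean and SD of each group of 4. In WAT the controls lie between 46.9 and 83.6 and the inhibitor libraries between 91.9 and 198.

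Among the genes recovered in both inhibitor groups, which lack most abundant genes, none passed for one inhibitor against the other. On recovered reads limma called 0 of 14917 genes in WAT and 0 of 12078 in BAT, with 284 and 56 at an unadjusted p under 0.05. Interferon response genes had a median log2 difference (antimiR-224 less antimiR-452) of 0.58 in WAT and -0.54 in BAT, with adjusted p of 0.589 and 0.211 with an estimated correlation. The effect of each inhibitor was then compared between tissues. The ratio of the deposited ratios gave 0 genes for antimiR-224 of 14152 and 0 for antimiR-452 of 14275 (235 and 128 at an unadjusted p under 0.05). In limma 0 genes passed for either, with 899 and 673 at an unadjusted p under 0.05.

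The log2 ratios of both inhibitors correlated across genes at 0.828 in WAT and 0.356 in BAT, genes not being independent replicates. Both use the same 4 controls, and simulated groups without any effect gave 0.497 (0.438 to 0.546) in WAT and 0.504 (0.456 to 0.553) in BAT. The covariance was 0.890 in WAT against a simulated 0.313, and 0.0830 in BAT against 0.172. With the recovered controls split into 2 and 2, the mean correlation over 6 splits was -0.03 in WAT (-0.32 to 0.25) and -0.04 in BAT (-0.57 to 0.21). At an unadjusted p under 0.05 and a mean of at least 10, 285 genes were higher with antimiR-224 and 628 with antimiR-452 in WAT, 230 of them with both. Simulated groups without any effect that share their controls gave 105 (85 to 121) for lists of these sizes, and independent lists, which leave out the shared controls, 10.2. The other overlaps lay within the simulated range: 14 lower genes in WAT (1 to 15), and in BAT 3 higher (1 to 10) and 2 lower (2 to 17). The overlap simulation drew genes independently, whereas sets such as the epithelium lists varied together between WAT libraries. Its range is therefore no bound on the overlap that such sets give without an effect. In BAT the correlation lay below its own simulated range, so that simulation did not match these data either. The excess of the higher WAT genes over either value is not a count of shared effects, and no gene passed an adjusted p of 0.05 for both.

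A further comparison asked whether transcripts with a match to the seed, the microRNA's pairing bases, in the 3' untranslated region differed from others. In WAT after antimiR-224, 2120 genes with a miR-224 site (GTGACTT) had a median log2 ratio 0.02 above that of genes of matched length and expression without it (permutation p 0.00680, adjusted p 0.0544). For the 410 genes with the longer site (GTGACTTA) the difference was 0.0150 (permutation p 0.326, adjusted p 0.773). In WAT after antimiR-452, the difference for 1495 genes with a miR-452 site (TGCAAAC) was -2.28e-04 (adjusted p 0.981). The miR-224 sites lay 0.01 above after antimiR-452 too (permutation p 0.0210, adjusted p 0.0840); with the longer site that difference was -0.0045. In BAT the difference was -0.01 for miR-224 sites after antimiR-224 (adjusted p 0.396) and -0.0049 for miR-452 sites after antimiR-452 (adjusted p 0.754). None of 8 such tests passed, and they treat genes as independent.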

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

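The explanations and splits tested in this part were chosen after the values of each library were seen. Of 128 groups of 4 libraries looked at, for some of the lists and genes reported, 8 held a library whose gap to the nearest of the others passed the 95% critical value of Dixon's test. Chance gives about 1 in 20, but other reported items were left out, so 8 is no count over all of them. Not looked at were, in WAT antimiR-452 libraries 1 to 4, B4galnt2 (344, 231, 213 and 0) and the circadian clock list (538, 546, 544 and 357).

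In WAT, antimiR-452 library 4 stood far below the other 3 for the ciliated epithelium list (3.27 against 301 to 488), the transporting tubule epithelium list (8.34 against 247 to 296), Dsp (23.3 against 1452 to 1857) and Dnah5 (0 against 749 to 982). The pattern behind these values is that ciliated and tubule genes were higher in both inhibitor groups on average. RNA of attached duct epithelium in some libraries is a candidate explanation: in the antimiR-224 group the ciliated list differed 28.5-fold, with 1 added to each geometric mean, between its highest and lowest library, and more in the antimiR-452 group. Dnah5 was at 1034 and 1106 in antimiR-224 libraries 1 and 2 and at 0 and 4.43 in libraries 3 and 4. A response to the inhibitors in every library is argued against, because 3 of the 8 inhibitor libraries lay below the highest control in the ciliated list. In the tubule list the same 3 were at 6.57 to 18.5, within the 6.05 to 42.2 of the controls, while the other 5 were at 247 or more. This holds for the lists as sets: Atp6v0a4, a member of the tubule list, was at 165 to 517 in all 8 inhibitor libraries against 38.5 to 112 in the controls. A response of that gene, which was picked from many by its small p, stays open. A response in only some mice stays open and was not tested. The lists were written after the data were seen, sperm-lineage cells also express genes of motile cilia, and control library 2 is high in both.

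In WAT, scramblemiR library 2 was far above the other 3 for the male germ cell list, at 1635 against 1.41 to 3.48. Prm1, a sperm protamine, was at 3001 there. No explanation was tested for this library.

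In BAT, antimiR-224 library 1 stood far above the other 3 for the less abundant skeletal muscle genes, at 254 against 5.45 to 7.50. Skeletal muscle carried along with some BAT samples is a candidate explanation, since the same list differed 228-fold, with 1 added to each geometric mean, between the scramblemiR libraries, which received neither inhibitor. A response to the inhibitors cannot be told apart from it, because 6 of the 8 inhibitor libraries lay within the range of the controls and that range is so wide. The most abundant muscle genes followed the same libraries: Acta1 was at 163092 and 174138 in control libraries 1 and 2 and at 87.9 and 178 in libraries 3 and 4.

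In BAT, antimiR-452 library 3 had 162 normalized counts of the Y-linked gene Eif2s3y, far below the 1396 to 1708 of the other 3, with 879 to 1386 in the controls. Ddx3y, also Y-linked, was at 675 there and at 2463 to 3222 in the other 3. No explanation was tested for this library.

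In BAT, antimiR-452 library 1 stood far above the other 3 for insulin signalling and glucose uptake, at 731 against 493 to 506. This is also the library of its group with the most muscle transcripts. No explanation was tested for it.

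The limma calls on recovered reads were compared with other splits of the same 8 libraries, and chance cannot be excluded for any of them. The real counts were 0, so it was certain beforehand that all 35 of 35 splits would give as many in each of 6 comparisons, which decides nothing. At an unadjusted p under 0.05, where the real counts were above 0, splits with as many genes numbered 10, 15, 11 and 11 of 35 for WAT antimiR-224, WAT antimiR-452, BAT antimiR-224 and BAT antimiR-452. For one inhibitor against the other they numbered 23 in WAT and 31 in BAT. The highest other splits gave 2842, 3589, 1712, 2476, 3506 and 2035 genes against 927, 726, 702, 551, 284 and 56. At an adjusted p of 0.05 the highest other split gave 45 genes for WAT antimiR-224, 897 for WAT antimiR-452, 0 for BAT antimiR-224, 350 for BAT antimiR-452, and 4 in WAT and 0 in BAT for one inhibitor against the other. Splits that call 350 and 897 genes point to a structure of the samples other than the groups. For the effects compared between tissues, all 100 of 100 regroupings likewise had to give as many as the real 0, with at most 1 for antimiR-224 and 55 for antimiR-452. At an unadjusted p under 0.05, 14 and 26 of them gave as many as the real 899 and 673, at most 1649 and 2345.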

How the results depend on the processing

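All settings on recovered reads and the adjusted p of 0.2 were chosen after the data were seen; the others beforehand. For WAT antimiR-224 the count of 1 gene was 0 at an adjusted p of 0.01 and 0 with limma on recovered reads, where the gene could not be tested. An unadjusted p of 0.05 gave 452, 702, 276 and 121 genes for WAT antimiR-224, WAT antimiR-452, BAT antimiR-224 and BAT antimiR-452, by construction. An adjusted p of 0.2 gave 2, 38, 0 and 0. An adjusted p of 0.1, a log2 ratio of at least 1 and both recomputed adjustments left these 4 counts as they were.

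On recovered reads the count of 0 for WAT antimiR-452 ranged from 0 to 543 with each library left out (543 without antimiR-452 library 4). Without the 3 libraries high in germ cell genes WAT antimiR-224 gave 1245, a fit with just 2 inhibitor libraries, both high in epithelium genes. The interaction ranged from 0 to 1 for antimiR-224 (1 without BAT scramblemiR library 4) and from 0 to 24 for antimiR-452 (24 without WAT antimiR-452 library 4). Without a minimum mean, WAT antimiR-224 against antimiR-452 gave 2. All other limma settings gave 0. Counts at an unadjusted p under 0.05 against scramblemiR also moved with each library left out. In WAT they ran from 488 to 2230 for antimiR-224 and from 324 to 1787 for antimiR-452. In BAT they ran from 230 to 1151 for antimiR-224 and from 185 to 1504 for antimiR-452. The cause of these moves was not tested.

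With the controls split, the correlation of both inhibitors' ratios turned from positive to -0.0286 in WAT and -0.0394 in BAT; each inhibitor then has 2 controls of its own. Counts of lists called by camera, adjusted over the fixed lists alone, were 0 in all 4 comparisons with an estimated correlation, and were 10, 5, 2 and 5 with a preset correlation (WAT antimiR-224, WAT antimiR-452, BAT antimiR-224, BAT antimiR-452). Camera tested just the lists with enough recovered members. Lists it could not test include fatty acid synthesis in WAT and skeletal muscle in BAT, so these counts are not all lost calls. For WAT antimiR-452 the mean in place of the median gave 5. On recovered reads 14, 13, 8 and 5 of 36, 35, 30 and 33 lists were called, and 11 to 15, 8 to 17, 4 to 15 and 4 to 10 with each library left out. Counts moved over 1.5 times without WAT scramblemiR library 3 or 4 (8 each) for WAT antimiR-452. For BAT antimiR-224 they did so without scramblemiR library 2 or antimiR-224 library 3 (15 each) or antimiR-224 library 4 (4). For BAT antimiR-452 they did so without scramblemiR library 4 (10), antimiR-452 library 1 (8) or library 3 (9). Of 202 alternatives for single lists, 154 kept the call, 46 lost it and 2 turned round: brown thermogenic genes in WAT antimiR-452 at a minimum mean of 50 (0.0780) and mesothelial markers there by the mean (0.20).

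The miR-452 site difference turned to 0.0035 in WAT antimiR-452 at a minimum mean of 50 and to 0.0061 in BAT antimiR-452 with the longer site, and the miR-224 site difference to -0.0045 in WAT antimiR-452 with the longer site. With the human seed the miR-452 difference was -0.0371 in BAT antimiR-452 (adjusted p 8.00e-04), past the threshold and opposite to a loss of repression. The causes were not tested. No paired analysis was possible because recovered reads cannot be tied to the numbers in the sample titles or the file headers. Tests on counts per sample with DESeq2 or edgeR, a fit of all 12 samples of a tissue on counts and the replicate block were not run.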

Other observations

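The tests of the clock genes in this part were chosen after the values were seen. In WAT, Arntl was higher in every inhibitor library than in any control. Its partner Npas2 had log2 differences of 1.26 and 1.51 in recovered reads (exact permutation p 0.0857 and 0.0286). The other genes looked at in the phase of Arntl moved less. Their log2 ratios with antimiR-224 and antimiR-452 in the authors' deposited tables were 0.09 and 0.17 for Cry1, 0.17 and -0.04 for Clock, and 0.65 and 0.27 for Nfil3.

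A candidate explanation is a different time of day of tissue collection between groups. The 8 clock genes of the opposite phase would then be lower by a log2 ratio of about 0.5 or more. Medians above -0.2 with both inhibitors would speak against it. The antimiR-452 median of -0.0818 lies above that bar, and none of its 8 genes reached -0.5 (lowest -0.24, Dbp). The antimiR-224 median of -0.23 lies between both bars, so the test over both inhibitors is undecided, and the bars themselves are assumed. Arntl was not higher on average in BAT (84.6 with scramblemiR, 44.7 and 81.9 with the inhibitors). That bears on collection time only for mice that gave both tissues, which the labels do not state, although 7 of 12 library numbers in the headers recur in the same treatment group of the other tissue. Collection times are not given in the sources used here, and a response of clock genes to the inhibitors cannot be told apart from them on these values.

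In WAT, the haemoglobin gene Hba-a1 was at 3151 to 14626 in the controls and at 739 to 2003 with antimiR-452, an adjusted p of 0.234 in the authors' deposited table.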
